A study of Mus musculus with 6 samples.

How the data were processed

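RNA from passage 1 lung fibroblasts of 3 wt and 3 ki mice was hybridised to Illumina mouse bead arrays after labelling as biotin cRNA, per the labels, with 1 array per mouse. The deposited intensity values of the non-normalised table were background-subtracted on a linear scale before deposit, as their negative values show (28.59% to 32.02% of probes per array), and were not normalised between arrays. The authors also deposited intensities normalised between arrays on a linear scale, and the series value table equals these in 100% of cells. The deposited detection p-value of each probe on each array, per the file headers, follows the rank of its signal among negative controls, in 936 steps. The scanner software, the background method and the normalisation method are not given in the sources used here. Detection reached 38.87% to 40.92% of the 45281 probes per array.

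The non-normalised intensities were background-corrected with limma 3.58.1 in R 4.3.3 (normexp, with the negative controls' mean and variance inferred from the detection p-values), raised by an offset of 16, quantile normalised and put on the log2 scale. A gene symbol was taken from the array annotation and updated through the gene identifier: 34885 probes carried 1 symbol, 18 several and 10378 none, and the last 2 kinds were left out of gene counts. Probes detected at p under 0.05 on at least 3 of the 6 arrays were tested, which left 18249 probes. Of a gene's probes the brightest was taken, giving 10412 genes.

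The genotypes were compared as ki minus wt with limma's linear model and moderated test, with 4 residual degrees of freedom and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 39 lists. The lists, of 935 names (2 matched no gene), and the rule for named genes were fixed before the data were examined. The rule named the 4 p38 kinases, up to 14 genes with the largest increase and 14 with the largest decrease among those passing with no overlap between genotypes, and up to 4 passing members of each list with the smallest p (up to 2 where none passed). Clone-named genes were passed over. Members named to complete a count of 5 or fewer, and Xist, were chosen after their values were seen. The number of arrays limits the precision: the median residual SD was 0.122 on the log2 scale, and the smallest change that passed was 0.258.

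The procedure was tested on simulated data in 5 runs. It found 25.57% of genes changed by 0.5 on the log2 scale and 96.16% of those changed by 1, and 4.57% of its calls were unchanged genes. It called 20 of 20 lists shifted by 0.4 (16 with an estimated correlation) and 0 of 148 others by camera with the preset correlation. The simulated noise was independent between probes, so these list counts do not cover lists whose genes vary together. Every member of a shifted list moved by 0.4, whereas the 8 lists called lower in the data had medians of -0.252 to -0.136. A first simulation counted background noise a second time and recovered few changes, so its noise model was revised once, after first differences between the genotypes had been seen, and the test procedure itself was left as it was.

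Alternatives tried were no further background correction, median scaling, the authors' normalised intensities, the series values, offset 50, no detection filter, detection at p under 0.01 on all 6 arrays, eBayes with trend and robust, array weights, a replicate block, leaving out each array, camera with an estimated correlation, fry, the mean of a gene's probes, counting probes, and 2 other thresholds. Median scaling over detected probes and leaving out the brightest wt and the dimmest ki array were chosen after seeing the data, as were 4 further gene lists and a histone group. No slide block was run because the headers name no slide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.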

Results

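Lung fibroblasts from 3 wild-type mice (wt, p38 +/+) and 3 mice homozygous for a p38 knock-in allele (ki) were profiled on Illumina bead arrays, 1 array per mouse. The animals were 10 weeks old, and the fibroblasts, the matrix-producing cells of the lung's connective tissue, were grown in medium with 15% fetal calf serum and collected at passage 1. p38 kinases are stress-activated protein kinases that act on transcription factors and on regulators of mRNA decay. The labels state neither which p38 gene carried the allele, nor the change it made, nor the sex of the mice. Each array held 45281 probes, of which 17601 to 18531 were detected above the negative controls. The mean background-subtracted signal was 846.7, 735.5 and 712.3 on wt arrays 1, 2 and 3, and 684.4, 519.4 and 694.7 on ki arrays 1, 2 and 3. The number of arrays limits the precision of every value below. All levels are normalised log2 intensities, differences are ki minus wt with their standard error (SE), and n = 3 mice per genotype throughout. For a probe detected on no array of a genotype, the fold is a lower bound against the lowest detected level on those arrays, written as at least.

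The first comparison asked how the transcripts of the p38 kinases themselves stood in the ki cultures, which bears on the labels. All 4 p38 genes were detected and none was lost in ki. Mapk13, which encodes p38 delta, was 1.79-fold higher in ki (log2 difference 0.84, SE 0.14, adjusted p = 0.0102), and its other detected probe gave 0.88. Mapk14, which encodes p38 alpha, was 1.22-fold higher (0.29, SE 0.070, adjusted p = 0.0368), from 11.69 ± 0.031 in wt to 11.98 ± 0.040 in ki (SD). The Mapk11 probe differed by 0.22 (SE 0.14, adjusted p = 0.353) and the brightest Mapk12 probe by -0.18 (SE 0.091, adjusted p = 0.24), neither past the threshold. Of the other Mapk12 probes, 1 gave -0.35 and 1, detected on 2 arrays of each genotype, gave 0.27. The list of p38 kinases had 2 of 4 members higher and 0 lower, and the same counts adjusted over the list alone (camera adjusted p = 0.228). The Mapk14 difference missed the threshold when any 1 array was left out (adjusted p 0.064 to 0.113). It was 0.012 under scaling to each array's median, which lies near background, and 0.22 (adjusted p = 0.0858) under scaling over probes detected on all 6 arrays. Its adjusted p ran from 0.00127 to 0.969 over the alternatives, so its size and its call depend on the normalisation. Mapk13 passed in all 18 alternatives, with differences of 0.648 to 0.958. Because the allele's sequence and the probes' positions relative to it are not given in the sources used here, these levels do not test the allele.

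**Figure D1:**
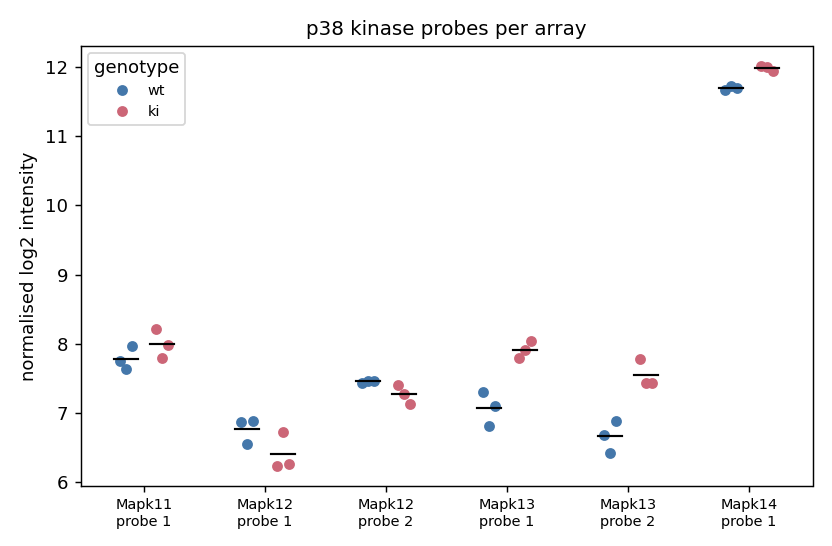
Normalised log2 intensity (y axis) of each p38 kinase probe detected on all 6 arrays (x axis), with 1 point per array in blue for wt and red for ki and a bar at each group's mean. Both Mapk13 probes lay higher on every ki array, Mapk14 differed by 0.29, and the Mapk11 and Mapk12 probes did not pass the threshold.

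The second comparison asked which other transcripts differed between the genotypes. In the ki cultures, keratins and surface proteins of mesothelial and epithelial cells were among the transcripts with the largest increases. The largest decreases included S100a9, Mpo and Ctsg, which neutrophils express, and the hyaluronan synthases Has1 and Has2 and the growth factor Fgf10 fell. Macrophage transcripts were bright in both genotypes, with Lyz2 at 15.965 in wt and 16.013 in ki and C1qb at 14.624 and 14.336. All 19 measured macrophage genes were detected on every ki array, so no difference here is assigned to fibroblasts alone. Of 10412 genes tested, 1625 (15.61%) passed the threshold, 870 higher and 755 lower in ki. Among them 145 were at least 2-fold higher and 120 at least 2-fold lower, and 26 and 19 changed at least 4-fold. The 3 ki arrays lay on one side of the 3 wt arrays for all 1625 of these genes, which the threshold nearly requires, and for 38.44% of all genes tested. That share would be 10% on average if the arrays were interchangeable. Genes are not independent, and the excess covers any difference between the groups, not the genotype alone. Correlations between arrays, taken across the 18249 detected probes, which are not independent replicates, were 0.9899 to 0.9943 within genotypes and 0.9791 to 0.983 between them. Scaling each array to its median gave 363 genes higher and 1318 lower, with the median gene at -0.22, where quantile normalisation had it at 0.007, and 12 of the 1625 genes changed sign. That median lies near background. Scaling over probes detected on all 6 arrays, chosen after seeing the data, gave 839 higher and 820 lower. The number of genes passing was 957, 953 and 972 without wt replicates 1, 2 and 3, and 513 without the brightest wt and the dimmest ki array, a choice made after seeing the data. Of the 194 passing genes covered by the naming rule or completing a count of 5 or fewer, 128 passed with each single array left out, and the other 66 missed the threshold without at least 1 array. Under scaling to each array's median 45 of the 194 missed it with their sign kept, and 2 more, Axl and Cdk2, changed sign and did not pass. Under scaling over detected probes 17 missed it.

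The largest increase was that of Sprr1a, a cornified envelope protein of stressed squamous epithelium. It was not detected on any wt array and reached 9.42 ± 0.14 (SD) in ki, at least 12.8-fold higher (adjusted p = 3.25e-05). Upk3b and Upk1b, uroplakins of urothelium and mesothelium, were 7.47-fold and 7.36-fold higher. Krt8 and Krt18, which pair as the keratins of simple epithelia, were 6.74-fold and 6.79-fold higher, and Krt19 was at least 5.87-fold higher, with no wt array above background. The mesothelial surface protein mesothelin (Msln) rose 6.56-fold, the tight junction protein Cldn6 6.28-fold, the anchoring protein Akap5 5.26-fold, the Src family kinase Fgr 5.19-fold and the extracellular matrix protein Thsd4 4.89-fold. The membrane glycoprotein Gpm6a, detected on no wt array, rose at least 3.87-fold. The atrial myosin light chain Myl7 and the potassium channel Kcnk1 were detected on 1 and 2 wt arrays and all ki arrays. Their size is therefore uncertain, with fitted log2 differences of 2.193 to 3.608 and 1.909 to 2.88 over the alternatives.

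In the other direction, the skeletal myosin light chain Myl1 fell from 9.53 ± 0.090 (SD) in wt to below detection on all 3 ki arrays, at least 13.7-fold (adjusted p = 1.19e-05). S100a9, a calcium-binding protein of neutrophils and monocytes, was 15.1-fold lower. The neutrophil granule enzymes Mpo and Ctsg were at least 10.3-fold and 3.87-fold lower, and Ngp, another neutrophil granule protein, at least 4.555-fold, all 3 undetected in ki. Ltf, the granule protein lactoferrin, was lower and was detected on 2 ki arrays, with fitted log2 differences of -3.168 to -1.927 over the alternatives. Stfa1 and Cstdc4, cysteine protease inhibitors of the stefin A type, were 13.1-fold and 7.12-fold lower. Stfa2 and Csta2, of the same type, were lower too and were detected on 1 and 2 ki arrays, with fitted log2 differences of -4.118 to -2.898 and -2.867 to -1.672. These genes have near-identical copies that probes may not tell apart, and the probe for Stfa3 was detected on no array. Macrophage and leukocyte markers fixed beforehand went both ways on the same arrays, with 5 of 26 higher and 5 lower. Also lower were the ecto-nucleotidase Nt5e (5.07-fold), the secreted BMP-related factor Gdf10 (4.81-fold), the phosphatase Alpl (4.67-fold) and the lipase Lipf (at least 3.59-fold, undetected in ki).

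**Figure D2:**
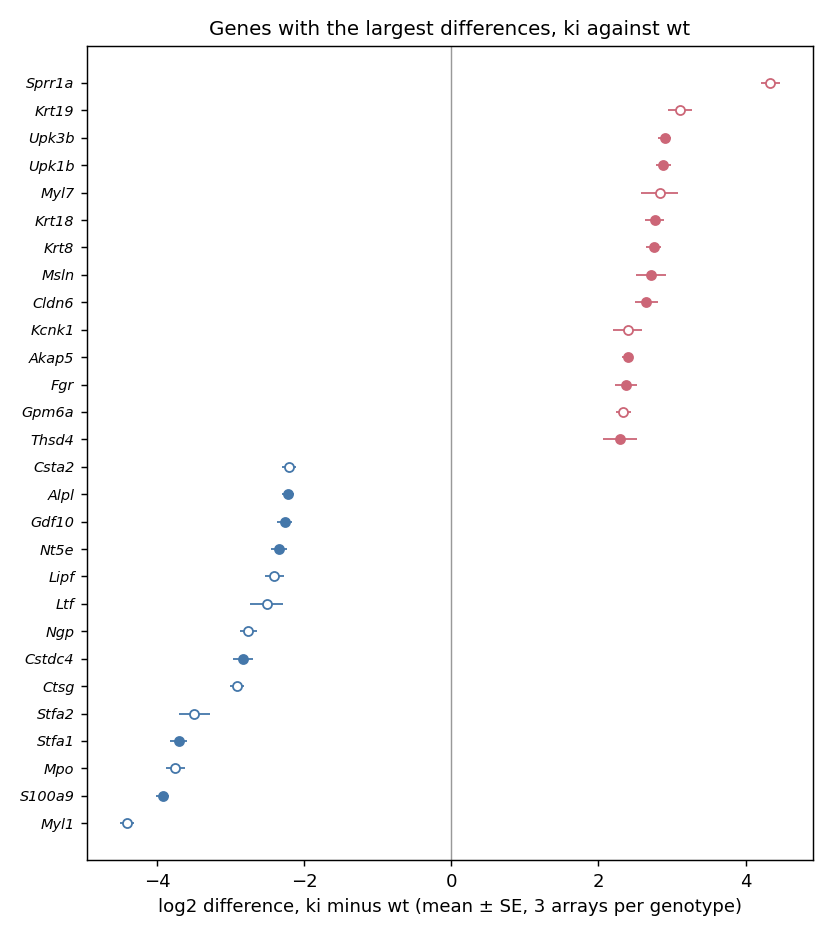
Log2 difference, ki minus wt, with its SE (x axis) for the 14 genes with the largest increase and the 14 with the largest decrease (y axis), red where higher and blue where lower in ki. Open circles mark genes not detected on every array of each genotype, whose fitted difference is not a bound, and the values run from 4.33 for Sprr1a to -4.41 for Myl1.

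Mesothelial markers, genes of the cells that line the pleura, rose as a group. Of 12 measured, 11 rose and 1, Igfbp5, fell (log2 difference -1.63, SE 0.074), with the same counts adjusted over the list alone. The median member was 5.76-fold higher, or 4.78-fold with Krt19 and Gpm6a, undetected in wt, at their bounds (camera adjusted p = 7.87e-11, adjusted p = 0.0932 with an estimated correlation). Besides the uroplakins, keratins and mesothelin, the list held the transcription factor Bnc1 (1.96, SE 0.083, adjusted p = 6.84e-05). Epithelial markers, which share Krt8, Krt18 and Krt19 with that list, rose too, with 11 of 18 higher and 0 lower, and 12 and 0 adjusted over the list alone (camera adjusted p = 1.09e-09, adjusted p = 0.0831 with an estimated correlation). The claudins Cldn4 and Cldn3, tight junction proteins, rose 4.23-fold and 3.92-fold.

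Genes of DNA replication and of mitosis were higher in ki on the same arrays as the mesothelial markers. Of 29 replication genes, 20 rose and 0 fell, and 25 rose adjusted over the list alone, with a median log2 difference of 0.56 (camera adjusted p = 1.44e-11, adjusted p = 0.0932 with an estimated correlation). Uhrf1, which maintains DNA methylation through replication, rose 1.91-fold (0.94, SE 0.080, adjusted p = 0.000887), thymidine kinase Tk1 1.89-fold, and the helicase component Mcm2 1.70-fold, from 8.35 ± 0.076 to 9.12 ± 0.040 (SD). Of 21 mitosis genes, 16 rose and 0 fell, with 18 higher and 1 lower adjusted over the list alone and a median log2 difference of 0.59 (camera adjusted p = 1.09e-09, adjusted p = 0.0823 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, rose 1.78-fold and the kinesin Kif2c 1.76-fold. The list of CDK inhibitors and G1 cyclins had 3 of 16 higher (Cdkn2b, Ccnd1 and Cdk2) and 1 lower (Cdkn2c), the same adjusted over the list alone (camera adjusted p = 0.133). Cdkn2b, an inhibitor of cyclin D kinases, was 2.08-fold higher, and Ccnd1, which encodes cyclin D1, was 1.74-fold higher. Cdk2 was at -0.001 under scaling to each array's median, and 1 of its 4 probes went the other way. Cdk2 and Cdkn2c missed the threshold with any 1 array left out (adjusted p up to 0.122). Among p53 targets 5 of 21 rose (Gtse1, Polk, Fas, Trp53inp1 and Ccng1) and 1, Plk3, fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.105), with Gtse1, a regulator of the late cell cycle, 1.68-fold higher. Polk, Fas, Ccng1 and Plk3 missed the threshold with at least 1 array left out (adjusted p up to 0.097), and 1 of 3 Fas probes went the other way. With median scaling Ccnd1 (0.484, adjusted p = 0.0566), Polk, Fas, Trp53inp1 and Ccng1 missed the threshold. The Y-linked gene Eif2s3y was higher in ki on these arrays too, and wt and ki cultures differed in mesothelial markers, so neither difference can be set apart from the genotype here.

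On the arrays where 11 of 12 mesothelial markers were higher (median log2 difference 2.53), several lists of matrix, contractile and growth factor genes had more members lower than higher in ki, and a different mix of cells is not set apart from the genotype for any of them. Of 16 fibrillar and basement membrane collagens, 6 fell and 2, Col14a1 and Col8a1, rose, with 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.158 with an estimated correlation). Col1a2, a chain of type I collagen, was 2.33-fold lower (-1.22, SE 0.11, adjusted p = 0.00117), Col5a2 was 1.45-fold lower, and Col14a1, a fibril-associated collagen, was 1.71-fold higher. Enzymes of collagen crosslinking and maturation had 3 of 16 lower (P4ha2, P4ha1 and Lox) and 0 higher, and the same adjusted over the list alone (camera adjusted p = 0.0131, adjusted p = 0.158 with an estimated correlation). The prolyl hydroxylase P4ha2 was 1.51-fold lower. Without the brightest wt and the dimmest ki array the collagen call was lost (adjusted p = 0.0571, range 0.00207 to 0.158 over the alternatives), and with scaling to each array's median the crosslinking call was lost (adjusted p = 0.0809, range 0.000624 to 0.158). Col8a1 and Lox missed the threshold with at least 1 array left out (adjusted p up to 0.116). The matrix glycoprotein and proteoglycan list had 6 of 24 lower and 4 higher (Efemp1, Ogn, Ltbp2 and Thbs2), 8 and 5 adjusted over the list alone (camera adjusted p = 0.133). Its hyaluronan synthases Has2 and Has1 fell 4.01-fold and 3.60-fold, and the glycoprotein tenascin C (Tnc) 1.87-fold. Efemp1 was undetected in wt and Ltbp2 detected on 1 wt array, and Ltbp2 and Thbs2 missed the threshold with at least 1 array left out (adjusted p up to 0.116). With median scaling Col8a1, Ogn and Thbs2 missed it (adjusted p up to 0.994). Among matrix proteases and their inhibitors 9 of 23 fell and 3 rose (Mmp12, Plat and Timp3), 10 and 4 adjusted over the list alone (camera adjusted p = 0.2). The elastase Mmp12 rose 4.24-fold and the plasminogen activator Plat 2.39-fold, while Mmp10, a stromelysin, fell 2.10-fold.

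Of 23 myofibroblast and contractile genes 7 fell and 1, the intermediate filament desmin (Des), rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0128, adjusted p = 0.158 with an estimated correlation). The collagen receptor subunit Itga11 fell 4.12-fold, from 12.4 ± 0.066 to 10.3 ± 0.015 (SD), and the myosin light chain kinase Mylk 1.79-fold. Of 11 pericyte and smooth muscle markers 3 fell (Cox4i2, Myh11 and Actg2) and 2 rose (Des and Mcam), with 5 and 2 adjusted over the list alone (camera adjusted p = 0.42). Fibroblast identity markers had 6 of 21 lower and 4 higher (Dpp4, Col14a1, Pi16 and Inmt), 7 and 4 adjusted over the list alone (camera adjusted p = 0.476). Dpp4, a surface peptidase of adventitial fibroblasts, rose 3.88-fold, and Thy1, a fibroblast surface glycoprotein, fell 1.51-fold. Myh11, Mcam, Pi16 and Inmt missed the threshold with at least 1 array left out (adjusted p up to 0.12), and Des, Mcam, Pi16 and Inmt with median scaling (0.0504 to 0.795).

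Of 27 growth factors and receptors 9 fell and 4 rose (Fgf18, Nrg1, Pdgfb and Fgf2), with 12 and 4 adjusted over the list alone (camera adjusted p = 0.0141, adjusted p = 0.158 with an estimated correlation). Fgf10, a mesenchymal factor needed for lung branching, fell 3.74-fold (-1.90, SE 0.068, adjusted p = 3.25e-05), Igfbp5 3.09-fold, Fgf7 1.89-fold and Igfbp4 1.81-fold. Fgf18, detected on 2 wt arrays, Nrg1, Pdgfb and Fgf2 missed the threshold with at least 1 array left out (adjusted p up to 0.125). Developmental transcription factors had 7 of 23 lower and 1, Gata6, higher, 9 and 2 adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.28 with an estimated correlation). Foxf1 and Tbx3, factors of lung mesenchyme, fell 1.65-fold and 1.64-fold. That list's call was lost without ki replicate 2 (adjusted p = 0.076), without the brightest wt and the dimmest ki array (adjusted p = 0.127) and with scaling to each array's median (adjusted p = 0.0809), in a range of 0.00706 to 0.28 over the alternatives. Wnt and BMP signalling genes went both ways, with 6 of 18 higher, 5 lower (Grem1, Bmper, Ccn4, Sfrp1 and Rspo3) and 6 and 6 adjusted over the list alone (camera adjusted p = 0.786, median -0.12 and mean 0.045), and the direction given by camera turned under 1 scaling. Bmp4 rose 1.69-fold and the BMP antagonist Grem1 fell 2.35-fold, while Bmper, Sfrp1 and Rspo3 missed the threshold with at least 1 array left out (adjusted p up to 0.143). With median scaling Bmp4 (0.461, adjusted p = 0.0722), Gata6 (0.461, adjusted p = 0.0724), Fgf2, Pdgfb and Nrg1 missed it. Among TGF-beta targets 8 of 21 rose and 3 fell (Snai1, Inhba and Pmepa1), 8 and 5 adjusted over the list alone (camera adjusted p = 0.778). The helix-loop-helix inhibitor Id1 rose 2.79-fold and the transcriptional repressor Snai1 fell 2.15-fold. Of 16 YAP-TEAD targets 1, Axl, rose and 3 fell (Nt5e, Amotl2 and Lats2), the same adjusted over the list alone (camera adjusted p = 0.133). Axl was at -0.002 under scaling to each array's median, and its other probe differed by -0.018. Axl, Amotl2, Lats2 (detected on 1 ki array), Inhba and Pmepa1 missed the threshold with at least 1 array left out (adjusted p up to 0.144).

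**Figure D3:**
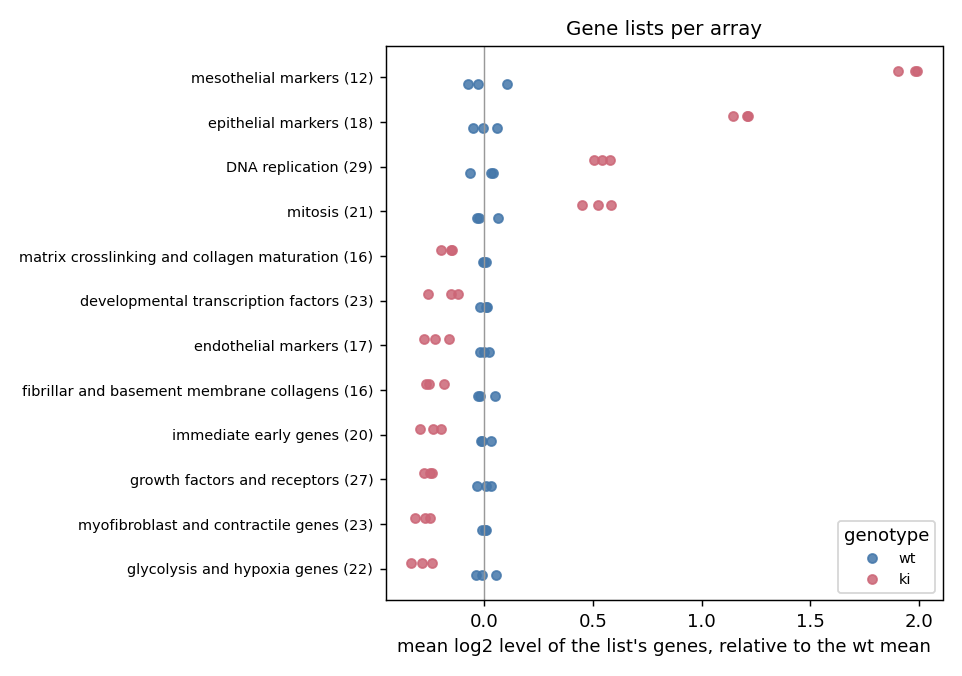
Mean log2 level of each gene list's measured members relative to the wt mean (x axis), with 1 point per array in blue for wt and red for ki, for the 12 lists called with a preset correlation (y axis, number of members in parentheses). The ki arrays lay between 1.90 and 1.99 for the mesothelial markers and on the far side of all wt arrays for each list shown.

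Immediate early genes, the first to answer growth and stress signals, had 5 of 20 lower (Nr4a2, Egr3, Jund, Myc and Junb) and 0 higher, and 8 lower adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.158 with an estimated correlation). Egr3 fell 1.88-fold (-0.91, SE 0.077, adjusted p = 0.000872), and Nr4a2 and Myc were detected on 2 and 1 of the ki arrays. Nr4a2, Jund, Myc and Junb missed the threshold with at least 1 array left out (adjusted p up to 0.121). The list's call was lost with detection required at p under 0.01 on all arrays (adjusted p = 0.0945) and with the mean of a gene's probes (adjusted p = 0.0512), in a range of 0.00188 to 0.158. Mesothelial and epithelial markers were higher on these arrays, so for this list too a different mix of cells is not set apart from the genotype. Activators and substrates of p38 had 1 of 18 lower, the mRNA decay factor Zfp36, and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.78). Of 10 dual-specificity phosphatases, which switch off MAP kinases, 2 rose (Dusp4 and Dusp14) and 1 fell (Dusp10, 1.74-fold), with 3 and 2 adjusted over the list alone (camera adjusted p = 0.732). Zfp36 missed the threshold without any array but wt replicate 3 (adjusted p up to 0.0712), Dusp4 without wt replicate 2 (0.0579) and Dusp14 without wt replicate 1 (0.053). With median scaling Dusp4 and Dusp14 missed it as well (0.291 and 0.244).

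Cytokines and chemokines changed in both directions, with 7 of 23 higher and 6 lower, 7 and 7 adjusted over the list alone (camera adjusted p = 0.731, median 0.11 and mean -0.003). The neutrophil chemoattractant Cxcl1 and the macrophage growth factor Csf1 rose 2.16-fold and 2.00-fold, and Cxcl14 and the alarmin Il33 fell 2.40-fold and 1.68-fold. Among NF-kB targets 6 of 20 rose and 2 fell (Lcn2 and Ptgs2, the latter detected on 1 ki array), 10 and 2 adjusted over the list alone (camera adjusted p = 0.0799). Tnfaip3, a feedback inhibitor of NF-kB, rose 1.74-fold, and Lcn2, also a neutrophil granule protein, fell 2.28-fold. Of 27 interferon-stimulated genes 3 rose (Gbp3, Gbp2 and Ifit2) and 1 fell (Trim30a), 6 and 2 adjusted over the list alone (camera adjusted p = 0.199). MHC class I and antigen processing genes had 1 of 14 higher (Psmb10) and 1 lower (Nlrc5), the same adjusted over the list alone (camera adjusted p = 0.78). The complement and coagulation list had 3 of 15 higher (Masp1, C4b and C2) and 2 lower (Cd55 and C1qa), 3 and 5 adjusted over the list alone (camera adjusted p = 0.407). In the list of 26 macrophage and leukocyte markers, 7 were higher and 8 lower adjusted over the list alone (camera adjusted p = 0.78, median -0.026 and mean 0.042). Cd74, the class II invariant chain, rose 2.50-fold, and H2-Aa (detected on 2 wt arrays), Ccr2, Aif1 and Adgre1 also passed. H2-Ab1 fell 1.56-fold, the chitinase-like protein Chil3, of macrophages and neutrophils, 2.19-fold, and C1qc, Itgam and C1qa also passed. Ccr2 was undetected in wt, and 1 of 3 Adgre1 probes went the other way. With at least 1 array left out Ptgs2, Ifit2, Trim30a, Psmb10, Nlrc5, C1qa, Itgam, Ccr2, Aif1 and Adgre1 missed the threshold (adjusted p up to 0.132). With median scaling Gbp3, Gbp2, Ifit2, Psmb10, C4b, C2, Aif1, Adgre1 and Itgam missed it (adjusted p up to 0.807). The direction given by camera turned under at least 1 scaling for the cytokine, MHC class I and macrophage lists.

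Glycolysis and hypoxia genes had 5 of 22 lower (Pkm, Ndrg1, Vegfa, Egln3 and P4ha1) and 0 higher, and 8 lower adjusted over the list alone (camera adjusted p = 0.000114, adjusted p = 0.161 with an estimated correlation). Of these, pyruvate kinase Pkm is a glycolytic enzyme, and the other 4 are known as hypoxia-responsive genes. Pkm fell 2.04-fold (-1.03, SE 0.079, adjusted p = 0.000576) and Vegfa, an angiogenic factor, 1.65-fold. Mesothelial markers were higher on the same arrays, and a different mix of cells is not set apart from the genotype for the glycolysis and hypoxia list. Of 29 oxidative phosphorylation genes and 25 cytosolic ribosomal protein genes, 0 passed in either direction with limma, over all genes and adjusted over the list alone, and 0 of each had an unadjusted p under 0.05. Their camera adjusted p were 0.146 and 0.731 and their fry adjusted p 0.00328 and 0.275. The direction of both lists turned under each scaling to a median. Ndufv1 differed by 0.17 (adjusted p = 0.184) and Rps24 by 0.13 (adjusted p = 0.317). Of 18 cholesterol synthesis genes 2 rose (Idi1 and Fdps) and 0 fell, 4 and 0 adjusted over the list alone (camera adjusted p = 0.0519). That list passed with camera in 7 of 20 alternatives, among them the fit without ki replicate 3 (adjusted p = 0.0303), in a range of 0.012 to 0.342. Among fatty acid and adipogenic lipid genes 3 of 14 rose (Elovl6, Scd2 and Acly) and 5 fell (Dgat2, Fabp5, Pparg, Cebpb and Dgat1), 4 and 5 adjusted over the list alone (camera adjusted p = 0.346). Dgat2, which makes triglycerides, fell 2.57-fold. NRF2 and glutathione genes had 5 of 23 higher (Gsta4, Gsta3, Gpx2, Mgst1 and Taldo1) and 3 lower (Hmox1, Abcc1, detected on 1 ki array, and Slc7a11), 5 and 4 adjusted over the list alone (camera adjusted p = 0.78), with the glutathione transferases Gsta4 and Gsta3 2.25-fold and 2.18-fold higher. The unfolded protein response and ATF4 list had 4 of 26 lower and 1, Chac1, higher, the same adjusted over the list alone (camera adjusted p = 0.632, median 0.007 and mean -0.041). Ddit4, a stress-induced inhibitor of mTOR signalling, fell 1.99-fold, and Trib3, Manf (undetected in ki) and Dnajb9 also passed. Of 14 heat shock proteins 1, Cryab, rose and 2 fell (Hspa1a and Hsph1), the same adjusted over the list alone (camera adjusted p = 0.802). Idi1, Fdps, Acly, Scd2, Pparg, Cebpb, Dgat1, Taldo1, Abcc1, Slc7a11, Trib3, Manf, Dnajb9 and Cryab missed the threshold with at least 1 array left out (adjusted p up to 0.144). With median scaling Idi1, Fdps, Elovl6, Acly, Scd2, Mgst1, Taldo1, Abcc1, Chac1, Manf and Cryab missed it (adjusted p up to 0.76). The other probe of Fdps and that of Dnajb9 went the other way, and the NRF2 list's direction turned under 1 scaling.

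Among the lists for other cell types, endothelial markers had 3 of 17 lower (Plvap, Flt1 and Robo4) and 0 higher, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.158 with an estimated correlation). Plvap, a protein of endothelial fenestrae, fell 2.17-fold (-1.12, SE 0.11, adjusted p = 0.00122). With scaling to each array's median that list's call was lost (adjusted p = 0.0743, range 0.00154 to 0.158 over the alternatives). Of 5 chondrocyte and bone markers 1, Sox9, rose and 1, Alpl, fell, the same adjusted over the list alone (camera adjusted p = 0.802, median 0.094 and mean -0.34). The direction given by camera turned under 1 scaling for the bone list, and Sox9 missed the threshold without any of 4 arrays (adjusted p up to 0.0638) and with median scaling (0.601), and Robo4 without wt replicate 2 (0.0561). Some sex-linked transcripts differed between the genotypes. The Y-linked gene Eif2s3y was 3.08-fold higher in ki (1.62, SE 0.084, adjusted p = 0.000134), at 8.07 to 8.29 on wt arrays and 9.76 to 9.80 on ki arrays. Kdm5d, also Y-linked, was detected on 1 wt array and all ki arrays and was higher (adjusted p = 0.0337, up to 0.104 with 1 array left out). Xist, transcribed from the inactive X chromosome, was detected on all 6 arrays, and all 4 of its probes were lower in ki with no overlap between genotypes. Its brightest probe differed by -0.61 (SE 0.18, adjusted p = 0.0741) and another by -0.74 (adjusted p = 0.00955). The remaining probes differed by -0.79 and -0.48 (adjusted p = 0.0554 and 0.052). Xist and Eif2s3y were both detected on every array, so these levels do not assign 1 sex to any culture. Why both were detected was not tested, and the balance of the sexes between the genotypes is not known. A further probe of Eif2s3y was detected on 1 ki array only, a further Kdm5d probe on none, and of 4 Uty probes 1 was detected on 1 wt array and the others on none. The X-linked Eif2s3x, looked at beside its Y-linked copy, differed by -0.058 (SE 0.089, adjusted p = 0.716). The list of 3 measured sex-linked genes had 2 higher and 0 lower, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.2).

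Across the 39 lists, camera with a preset correlation called 12, of which 4 were higher and 8 lower. With a correlation estimated for each list it called 0 (11 at an unadjusted p under 0.05), and fry, which asks only whether a list's genes move one way on balance, called 28, all 12 among them. Besides cholesterol synthesis, 5 lists not called passed with camera in 1 or 2 alternatives: NF-kB targets (lowest adjusted p 0.0148, highest 0.565), matrix glycoproteins and proteoglycans (0.0287 and 0.288), YAP-TEAD targets (0.0171 and 0.271), p53 targets (0.0449 and 0.518) and sex-linked genes (0.00877 and 0.339).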

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

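Median scaling over detected probes and the fit without the brightest wt and dimmest ki array were chosen after the results were seen. Over the alternatives, 2950 values of named genes stayed on their side of the threshold, 554 no longer passed, 6 newly passed and 2 of passing genes reversed; for gene lists these counts were 768, 20, 30 and 0. The sign also changed in 4 values of genes not passing (Ndufv1, Cox6c, Rpl30 and Rps24) and 13 values of 9 lists not called. With median scaling 363 genes were higher and 1318 lower, Axl was at -0.002 and Cdk2 at -0.001, 1 p38 kinase gene passed and Mapk14 was at 0.012; this scaling centres on a median near background. Over detected probes it left 1 p38 kinase gene and Mapk14 at 0.22. With no detection filter, which tests more genes, 472 were lower, 1 p38 kinase gene passed and Mapk14 (0.292) missed the threshold. At least 2-fold changes numbered 176 with offset 50 and 163 with strict detection, against 265 genes. With trend and robust 1309 genes were higher. Same-number correlations between wt and ki replicates (0.004 to 0.105) lay within the range of the others (-0.116 to 0.109), which neither shows nor excludes pairing by number. The replicate block gave 490 lower, 1 p38 kinase gene and Mapk14 at 0.292 without passing. Leaving out 1 array each, which loses degrees of freedom, gave 953 to 1185 genes, 541 to 645 higher, 398 to 540 lower, 1 p38 kinase gene and Mapk14 at 0.277 to 0.315, not passing. Without the brightest wt and dimmest ki array these were 513, 287, 226, 1 and 0.269. Camera with an estimated correlation called 0 lists (11 at an unadjusted p under 0.05) and fry 28. Counting probes gave 2604, an adjusted p under 0.01 gave 694 and a 1.5-fold minimum 797. Where construction is not named, the cause was not tested. Signal near background limits genes undetected in a genotype to bounds.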

Other observations

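The tests on alveolar type 2 cells, on the median of the alveolar and airway transcripts, on leukocytes of every kind and on the neutrophil lineage were chosen only after the result was seen, as were the further gene lists. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05: 1 split, the real one, gave as many as 1625 genes, with 0 as the highest other count (219 to 436 at an unadjusted p under 0.05, against 3179), and 1 gave as many as 12 lists, with 4 as the highest other. Every other split mixes wt and ki arrays in both of its groups. A real difference then adds to the spread within groups, so the low gene counts of those splits do not measure chance.

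Mesothelial markers and keratins were higher in ki, with a median of 2.526 for the mesothelial list. Without the brightest wt and dimmest ki array it was 2.591, which argues against those arrays as its source. The remaining wt arrays were still brighter than the ki arrays, so brightness is not excluded. Of 5 abundant alveolar type 2 cell transcripts (Sftpc, Sftpb, Sftpa1, Slc34a2 and Lamp3) 0 was detected on any array, nor was Epcam. These 5 were chosen after the result was seen, and no array shows that their probes respond. The count therefore does not decide on type 2 cells, nor on type 2 cells that no longer express these genes. Napsa, another listed alveolar and airway transcript, was detected on every array. Whether alveolar or airway epithelial cells are present was left undecided by the planned test. Of 11 listed transcripts (9 shared with the epithelial list) 5 were detected on all ki arrays and 5 on all wt arrays. The 5 measured had a median of 0.126 (SD 0.554, with Napsa higher and Cbr2 lower). That lay below the mesothelial median by more than this SD, a bound set after the result was seen. With 5 alveolar and airway genes that went both ways, it cannot decide on a larger share of such cells in ki. A larger share of mesothelial cells may contribute (3 genes of the further list are also in the fixed lists): 2 of 12 further mesothelial genes were higher (Aldh1a1 and, detected on 1 wt array, Nkain1), with a median of 0.166 (SD 0.295). The further genes did not rise in step with the markers, but some were already bright in wt, such as Slpi (13.163) and Cpe (12.775). Added cells could move such genes little, so this median is weak evidence on the share of mesothelial cells. The planned test met neither of its bounds, and the markers that rose are themselves of these cells. That share cannot be told apart from a change within fibroblasts, and a sex difference was not tested.

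Of 19 measured genes of the neutrophil list, 14 were lower in ki at an adjusted p under 0.05 and 18 lay below 0, with a median of -1.755, or -1.188 with the 6 genes undetected in ki at their bounds. The 5 that did not pass were Prtn3, Mmp9, Cd177, Hp and Csf3r. The fall of 13 of the 19 had been seen before the list was written, so this count is not independent evidence. The median was -1.75 without the brightest wt and dimmest ki array, which argues against those arrays as its source. The remaining wt arrays were still brighter than the ki arrays, so brightness is not excluded. The 19 macrophage genes, all from the fixed list, had a median of -0.031 (SD 0.283, with Aif1 and Adgre1 higher and C1qc, Itgam and C1qa lower), which argues against fewer leukocytes of every kind. Fewer cells of the neutrophil lineage may be a source: of the 6 members not seen beforehand 1 was lower (Pglyrp1, undetected in ki; median -0.126), too few to decide.

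DNA replication and mitosis genes were higher in ki, with a median of 0.572 over all arrays and 0.579 without the brightest wt and dimmest ki array, which argues against those arrays as its source. The remaining wt arrays were still brighter than the ki arrays, so brightness is not excluded. No biological explanation was tested, and the mix of cells stays open.

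Of 41 measured replication-dependent histone genes, a group picked after seeing the data, 15 were higher and 3 lower (H2ac18, H2ac19 and H1f2), with a median of 0.114. Most of those higher were H2A genes (H2ac), and no H4 gene passed. H2A genes have near-identical copies that probes may not tell apart, so the count does not stand for as many separate changes. Of the 100 measured genes nearest Mapk14 in gene order 7 passed (Fisher's exact test, two-sided p = 0.0175, adjusted 0.035) against 15.61% of all genes, and of the 100 nearest Mapk12, 17 passed (p = 0.678, adjusted 0.678).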
